A study of Mus musculus with 87 samples.

How the data were processed

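The series holds 87 samples of mouse embryonic stem cells with genes for subunits of Polycomb repressive complex 2 (PRC2) knocked out. RNA was sequenced in 24 libraries, 3 for each of 8 genotypes, and each had a file of its own. The other 63 samples are chromatin immunoprecipitations; their own signal is not analysed here, and 3 peak lists of the whole series (SUZ12, JARID2 and PCL2) were used. Per the labels' protocols the cells grew on gelatin in medium with 2i inhibitors, and the RNA libraries came from total RNA with a TruSeq kit. The labels do not say whether the libraries of a genotype came from separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical. The strain label of the RNA samples also changes with the genotype, its last digit rising by 1 from each genotype to the next as a filled-down spreadsheet column would. Whether the strains differ is therefore unknown, and as labelled strain and genotype cannot be separated.

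The authors deposited whole-number read counts per Ensembl gene ID. The submitters' processing notes name STAR, HTSeq and the mm10 build for RNA, and Trimmomatic, Bowtie2 and mm10 for the immunoprecipitations, without versions. Strandedness of the counting is not given in the sources used here, so antisense and overlapping genes, and near-identical copies of a gene, are uncertain. The deposited peak lists, whose other values are positions in base pairs, hold a chromosome, a start and an end per peak. The peak caller, its threshold, and whether libraries were pooled are not given in the sources used here; the lists have no scores and no replicates.

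Neither the files nor the reference table pair the Ensembl IDs with symbols, so RNA results are given by ID and no symbol was guessed. The count of each targeted gene in its own knockout, the tests of fixed gene lists on RNA and the test of peak-bound genes among changed genes therefore could not be run. The rule for named genes, the gene lists and the planned comparisons with their alternatives were written before the data were examined. That rule took the targeted genes, the most changed IDs and members of fixed lists. What remains of it here is the 2 IDs with the highest and the 2 with the lowest log2 fold change in the Suz12 knockout, among IDs past the threshold with at least 1 CPM in one group and no overlap between libraries (10% of IDs by chance).

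Counts were analysed with edgeR 4.0.16 in R 4.3.3. Of 55450 IDs, 24056 had no count in any library, and 14650 passed filterByExpr with its default settings. These were scaled by the trimmed mean of M values (TMM) and fitted together over the 24 libraries with 1 mean per genotype, robust dispersions and the quasi-likelihood test. An ID was called past the threshold at a Benjamini-Hochberg adjusted p under 0.05, with no fold threshold. Total counts per library ran from 10148155 to 28442061. In 13 planned comparisons, 7 set a knockout against wild type (WT), 1 set the knockout of 6 non-core subunits against the Suz12 knockout, 4 followed the loss of a further subunit, and 1 tested whether 2 losses added up. One more, the difference between the effects of losing Epop in 2 backgrounds, was added after the calls had been seen. CPM are TMM-scaled read counts relative to library size; log2 CPM used a prior count of 2. Where all libraries of a group had 0 counts, the fold was computed against 3 counts over that group; with 1 or 2 counts the ratio has an exact 95% counting interval, which like that floor covers counting error only.

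Comparisons with WT share its 3 libraries. The similarity of each knockout to the Suz12 knockout is the Pearson r of log2 fold changes, across IDs, which are not independent replicates. In 100 simulations unchanged groups against the same WT gave values with no effect, from fold changes that spread less than the observed ones. With 3 libraries, WT cannot be split into parts of at least 2 libraries each, so part of any excess may come from the shared WT libraries. Sets chosen in Suz12 KO were also drawn in 20 simulations that gave the full non-core knockout the Suz12 KO means, added after the result was seen. For the 2 contrasts of 4 genotypes, log2 CPM residuals of the model without the interaction were permuted 99 times over the 12 libraries, and within replicate numbers, and tested with limma-trend, also added afterwards.

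Symbols and positions of genes came from a RefSeq table of the assembly GRCm38.p6, whose coordinates are those of mm10. All 21887 protein-coding genes on the autosomes, X and Y formed the background. The table gives no strand, so a gene was called near a peak when a peak lay within 1 kb of either end of it. This rule replaced a planned distance from the transcription start, after the files had been seen. Of 435 genes in the 23 fixed lists, the mitochondrial ones and Dux were not matched, and 22 lists were tested with Fisher's exact test (two-sided), adjusted over 22 lists and 3 proteins together. Peak lists were compared with bedtools 2.31.1 at an overlap of at least 1 bp, with 100 shuffles within chromosomes as background and 95% Wilson intervals. Positions are 1-based.

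Each step was tested on simulated data. With 200 of 14650 IDs changed, the simulated Suz12 knockout against WT recovered 20.9% of 1.5-fold, 59.7% of 2-fold and 83.3% of 4-fold changes, with 8 false calls. The simulated addition of Epop loss to Pcl1-3 loss recovered 32.8%, 52.2% and 81.8%. The simulated test of added losses recovered 4.48%, 41.8% and 77.3%. In the peak step all 2000 simulated genes matched a direct search, all 50 planted lists were found, and 1 of 50 random lists was called.

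Libraries of a genotype differed by more than sampling noise, with a chi-square per degree of freedom from 6.25 to 67.8, so none was counted as a duplicate. Replicate numbers come from the labels. By the rule that each of the 3 same-numbered correlations of deviations exceed 0.1, the numbers paired the Suz12 knockout with WT and 20 of 21 pairs of knockouts, but not WT with the other 6 knockouts. Alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, only the genotypes compared, the replicate number as a block, a log2 fold threshold of 1, leaving out each library, larger overlaps, wider peaks and other distances. Statistics also used Python 3.11.15, scipy 1.17.1, statsmodels 0.14.6, numpy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9.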

Results

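The series concerns PRC2, the complex that methylates histone H3 at lysine 27 and is held to keep developmental genes silent. SUZ12 is a core subunit. The non-core subunits lost here were the 3 Polycomb-like proteins PCL1, PCL2 and PCL3 (genes Phf1, Mtf2 and Phf19; their joint knockout is called Pcl1-3 KO), JARID2, AEBP2 and EPOP. Read counts were analysed for WT, Suz12 KO, Pcl1-3 KO, Pcl1-3 + Epop KO, Jarid2 + Aebp2 KO, Pcl1-3 + Jarid2 KO, Pcl1-3 + Jarid2 + Aebp2 KO and Pcl1-3 + Jarid2 + Aebp2 + Epop KO, the last called the full non-core knockout below. Each had 3 libraries. Total counts ran from 10148155 (WT replicate 2) to 28442061 (Pcl1-3 KO replicate 3). The peak lists held 7796 SUZ12 peaks (median width 1462.5 bp, 14.5 Mb in all), 4991 JARID2 peaks (1050 bp, 7.44 Mb) and 20003 PCL2 peaks (724 bp, 21.9 Mb).

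The peak lists show which genes lie near PRC2 and how far its subunits share sites. SUZ12 peaks lay within 1 kb of an end of 4520 of 21887 protein-coding genes (20.7%), JARID2 peaks of 2537 (11.6%) and PCL2 peaks of 7746 (35.4%). All 3 proteins had a peak near 2440 genes, SUZ12 and PCL2 without JARID2 near 1996, and PCL2 alone near 3231. Of SUZ12 peaks, 97.3% (95% Wilson interval 96.9 to 97.6) overlapped a PCL2 peak and 50.5% (49.4 to 51.6) a JARID2 peak, against 2.34% and 0.651% for shuffled peaks. Of JARID2 peaks, 89.1% (88.2 to 90.0) overlapped SUZ12 and 95.2% (94.5 to 95.7) PCL2, against 1.06% and 2.00%. Of PCL2 peaks, 39.2% (38.6 to 39.9) overlapped SUZ12 and 21.6% (21.0 to 22.2) JARID2, against 0.960% and 0.515%. SUZ12 peaks that overlapped both others had a median width of 2076 bp, those with PCL2 only 1052 bp, and 11828 PCL2 peaks without either had 506 bp. With no scores or replicates, the overlaps also depend on how many peaks each list holds; with peaks of at least 1 kb only, 73.8% of PCL2 peaks overlapped SUZ12.

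Developmental regulators were the groups most often near peaks. Among the 28 neural regulators, which specify neurons and brain regions, all had a SUZ12 peak and a PCL2 peak and 26 a JARID2 peak; Sox1, Pax6 and Olig2 had all 3 (adjusted p = 1.02e-18 for SUZ12, Fisher's exact test with Benjamini-Hochberg adjustment; n = 28 genes). Of 39 Hox genes, which pattern the body axis, 36 had SUZ12 (adjusted p = 2.01e-20), 35 JARID2 and 39 PCL2; Hoxc4, Hoxc12 and Hoxc13 had PCL2 without SUZ12 near an end, and Hoxc4 held a SUZ12 peak inside the gene. Of 28 primitive streak and mesoderm genes, 25 had SUZ12, 23 JARID2 and 26 PCL2, among them T, Eomes, Mixl1 and Hand1, while Tbx6 and Cdx1 had no peak of the 3. Of 30 signalling ligands and receptors, 25 had SUZ12, 24 JARID2 and 29 PCL2, including Shh, Wnt1, Bmp2 and Dll1; Epha4 had none. Of 13 Wnt targets, 11 had SUZ12, 8 JARID2 and 11 PCL2, with Lef1, Lgr5 and Cdx2 near all 3 and Axin2 without a peak near an end (PCL2 lay inside it). Each of these 5 lists passed for all 3 proteins. The test takes genes as independent, but Hox genes lie in clusters where a single wide peak can be near several of them. The p for Hox genes is therefore too small.

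Further lists covered early lineages, imprinted, germline and MAPK feedback genes. Of 22 endoderm genes, 14 had SUZ12, 13 JARID2 and 15 PCL2: Gata6, Sox17 and Foxa2 had all 3, and the secreted products Ttr and Afp had none. Of 18 trophoblast genes, 12 had SUZ12, 10 JARID2 and 13 PCL2, with Cdx2, Gata3 and Eomes near all 3 and Elf5 near none. Of 18 primed epiblast genes, 12 had SUZ12, 9 JARID2 and 14 PCL2; Fgf5, Otx2 and Pou3f1 had all 3, while Dnmt3b had no JARID2 peak. Of 27 imprinted genes, 18 had SUZ12, 13 JARID2 and 20 PCL2, among them Cdkn1c, Phlda2 and Grb10. These 4 lists also passed for all 3 proteins, with the largest adjusted p at 0.00600 (endoderm, PCL2). Of 23 germline genes, 10 had SUZ12 (adjusted p = 0.0322), 6 JARID2 (0.0760) and 18 PCL2 (9.92e-05). Of 11 MAPK feedback genes, 6 had SUZ12 (adjusted p = 0.0281), 4 JARID2 (0.0557) and 7 PCL2 (0.101), with Dusp4, Spry4 and Egr1 near SUZ12 and JARID2. The SUZ12 call for germline genes ended at 5 kb (adjusted p = 0.0859), over the whole gene (0.0841) and, with a smaller share of members near a peak than of other genes, with peaks wider than the median only (1), and held with peaks of at least 1 kb (0.0195). The PCL2 call for germline genes ended with peaks of at least 1 kb (0.611) and otherwise held at 4.55e-06 to 0.0124. The SUZ12 call for MAPK genes ended under each of the 4 other peak settings, at 0.0505 to 0.249.

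None of the 20 naive pluripotency genes, such as Pou5f1 and Nanog, had a SUZ12 or JARID2 peak near an end (adjusted p = 0.0428 and 0.237), although Esrrb held SUZ12 and JARID2 peaks inside the gene and Dppa3 a SUZ12 peak, and Klf4, Klf5, Tbx3 and Dppa3 had a PCL2 peak (0.247); under the other 4 settings the adjusted p for SUZ12 was 0.0690, 0.281, 0.119 and 0.269. Of 24 ribosomal protein genes, Rpl7 alone had SUZ12 (adjusted p = 0.0760) and PCL2 (0.00203, fewer than other genes; 0.125 with peaks of at least 1 kb, otherwise 0.000216 to 0.0317), and none JARID2. The genes of the 6 PRC2 core subunits, Suz12 and Ezh2 among them, had no peak of the 3 proteins, and neither did the 4 Y-linked genes; neither list passed. Of 8 PRC2 non-core genes, Phf19 and Ezhip had all 3, while Aebp2, Jarid2, Epop and Lcor had PCL2 alone near an end (Jarid2 held a JARID2 peak inside the gene; 6 had PCL2, adjusted p = 0.0505). Of 22 genes of PRC1, the other Polycomb complex, 8 had SUZ12 (adjusted p = 0.165), 7 JARID2 (0.0216) and 11 PCL2 (0.260), with Cbx2, Cbx8 and Bmi1 near all 3. The JARID2 call for PRC1 ended at 5 kb (0.0612) and held under the other 3 settings (0.0106 to 0.0183).

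Lists of other cell types and of stress mostly did not pass. Of 18 fibroblast genes, 5 had SUZ12, 6 JARID2 (adjusted p = 0.0277) and 8 PCL2, with Twist2, Fbn1 and Thy1 near SUZ12; the JARID2 call ended at 5 kb (0.0684) and over the whole gene (0.0663), and held with wider peaks (0.0179 and 0.0215). Of 16 blood and endothelial genes, 3, 1 and 7 had SUZ12, JARID2 and PCL2. Of 18 genes of 2-cell-like cells the numbers were 2, 1 and 2, of 19 cell cycle inhibitors and p53 targets 6, 3 and 7, and of 15 heat shock and unfolded protein response genes 3, 2 and 5. Cdkn2a, a cell cycle inhibitor, had a SUZ12 peak.

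**Figure D1:**
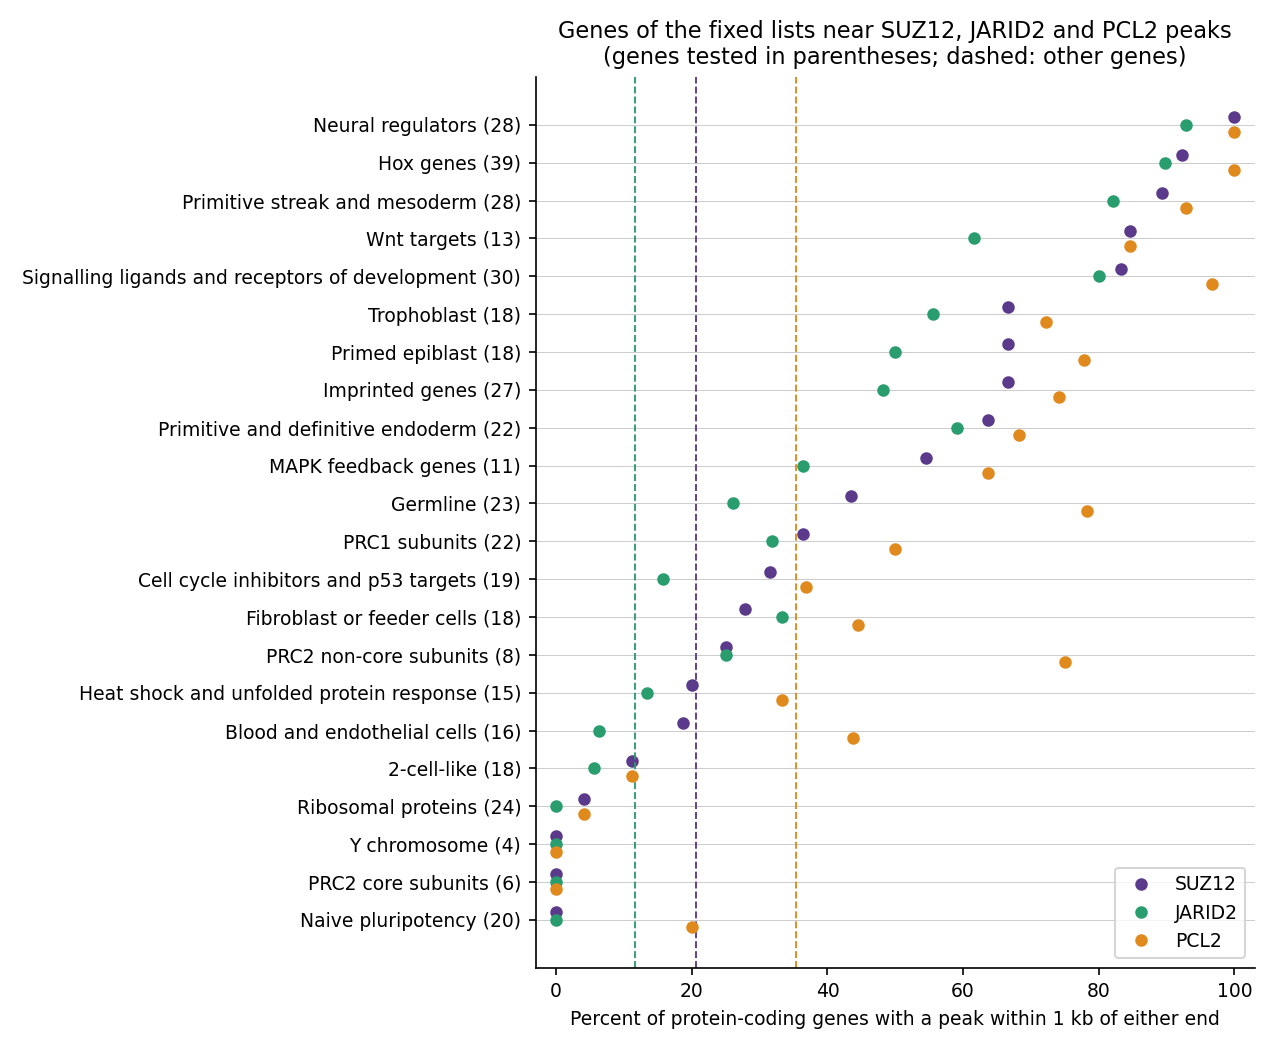
Percent of the protein-coding genes of each fixed list (vertical axis, number of genes in parentheses) with a SUZ12, JARID2 or PCL2 peak within 1 kb of either end (horizontal axis), with dashed lines for other genes. Neural regulators sit at 100% for SUZ12 and PCL2, and naive pluripotency genes at 0 for SUZ12 and JARID2.

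The Hox clusters held long stretches of SUZ12 (mm10 coordinates). The Hoxa cluster (chromosome 6, 52155367 to 52260880) was covered by SUZ12 peaks over 83.7% of its length, Hoxd (chromosome 2, 74668225 to 74765142) over 63.3%, Hoxb (chromosome 11, 96194316 to 96368254) over 42.0% and Hoxc (chromosome 15, 102921131 to 103036856) over 36.5%. JARID2 covered 68.3%, 59.8%, 33.6% and 20.7% of them in that order, and PCL2 70.3%, 63.9%, 46.0% and 46.5%. One SUZ12 peak of 55567 bp spanned chromosome 6, 52199714 to 52255280, from Hoxa3 toward the 5' Hoxa genes. The next widest, of 36048 and 29819 bp, lay on chromosome 6 at 47651102 to 47687149, by the Rn4.5s gene, and at 47736976 to 47766794, by predicted genes. Neither stretch was among the 10 widest JARID2 or PCL2 peaks, and whether misplaced reads from repeats made these peaks was not tested. Other wide SUZ12 peaks lay at Six3 (chromosome 17, 85607225 to 85626713), Uncx (chromosome 5, 139538937 to 139559168), Sox1 (chromosome 8, 12382347 to 12399889) and Ebf3 (chromosome 7, 137307759 to 137324162). The widest, 87992 bp at chromosome 8, 123536848 to 123624839, covered the tandem 5S ribosomal RNA genes, where reads from repeats cannot be placed uniquely.

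**Figure D2:**
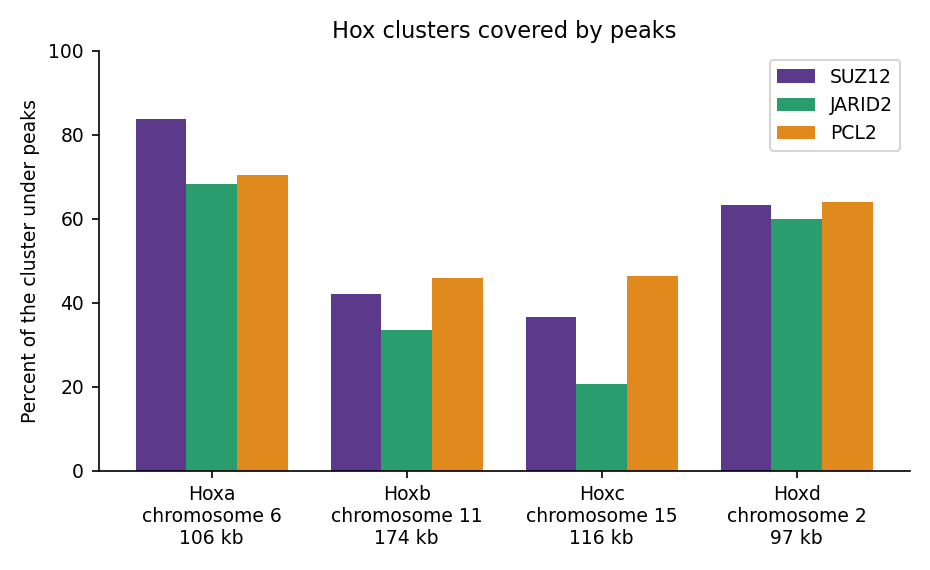
Percent of each Hox cluster (horizontal axis, with chromosome and length) under SUZ12, JARID2 and PCL2 peaks (vertical axis, bars start at 0; 1 list per protein, so no error bars). SUZ12 covered 83.7% of Hoxa and 36.5% of Hoxc.

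The first RNA comparison asks what the loss of the core subunit does. In Suz12 KO against WT, 3038 IDs rose and 2683 fell of 14650 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Of these, 2018 rose and 599 fell by more than 2-fold, and the median log2 fold change was 1.51 among risen and −0.63 among fallen IDs. Of 1172 IDs with a mean under 0.5 CPM in WT, 716 rose (61.1%), while of 502 under 0.5 CPM in Suz12 KO, 106 fell (21.1%). The filter on low counts raises both shares, since an ID nearly silent in 1 genotype passes it through others; without it 1405 of 17793 (7.90%) rose and 139 of 16683 (0.833%) fell. Of 4464 IDs over 50 CPM in WT, 268 rose and 1313 fell; WT both sets these classes and serves as control. By a stricter rule, from under 0.5 CPM in WT to at least 2 CPM with no overlap between libraries, 272 IDs gained and 14 lost expression (chance gives no overlap for 10% of IDs with 3 against 3). IDs at 1 CPM or more numbered 12347 ± 59.8 in WT and 13376 ± 179 in Suz12 KO (SD, n = 3), against group means of 12228 to 12535 in the other 6 knockouts. This count used CPM without the TMM factors. These were 1.07 to 1.09 in Suz12 KO and 0.974 to 0.995 in WT, so unscaled CPM favour more IDs in Suz12 KO.

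ENSMUSG00000021278.7 had 0 counts in WT and 5.57 ± 1.06 CPM (SD, n = 3) in Suz12 KO, at least 63.5-fold higher against 3 counts over the WT group (edgeR quasi-likelihood adjusted p = 1.47e-06), and 1.72 ± 0.40 CPM in the full non-core knockout. ENSMUSG00000031125.2 had 0 counts in WT and 4.03 ± 2.19 CPM in Suz12 KO, at least 46.1-fold higher (edgeR adjusted p = 1.35e-05), but 1 count in the full non-core knockout (edgeR adjusted p = 0.502). ENSMUSG00000107634.1 had 3.31 ± 0.51 CPM in WT (114 counts) and 1 count in Suz12 KO, a ratio of 160 (95% counting interval 28.1 to 6370; edgeR adjusted p = 2.10e-07), and 3.82 ± 0.64 CPM in Jarid2 + Aebp2 KO. It also fell in the 5 knockouts that lose Pcl1-3, to means of 0.0475 to 0.398 CPM (edgeR adjusted p from 1.01e-06 to 0.000177). ENSMUSG00000071424.10 had 1.02 ± 0.40 CPM in WT (36 counts) and 2 counts in Suz12 KO, a ratio of 25.2 (6.5 to 216; edgeR adjusted p = 0.000129).

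**Figure D3:**
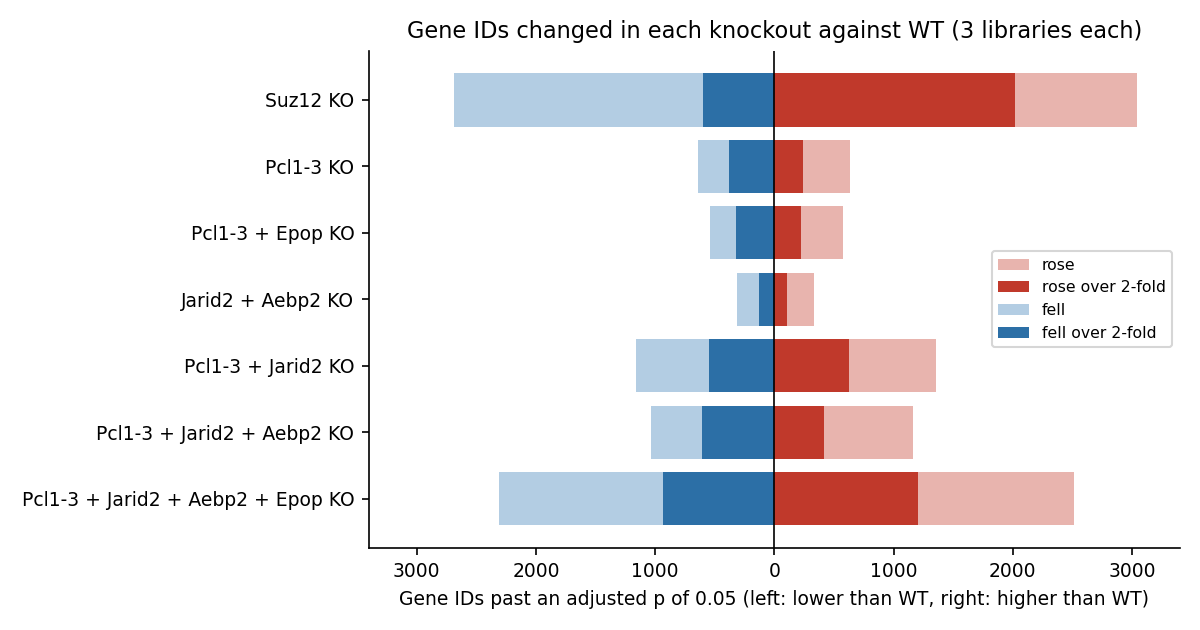
Number of gene IDs past an adjusted p of 0.05 in each knockout against WT (horizontal axis; right, higher; left, lower), with the part over 2-fold in the darker colour (3 libraries per genotype). Suz12 KO had 3038 risen IDs and Jarid2 + Aebp2 KO 331.

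The knockouts of single groups of non-core subunits changed fewer IDs. In Pcl1-3 KO against WT 637 IDs rose and 637 fell (1274 in all), with 238 and 382 past 2-fold, and 39 IDs lost expression by the stricter rule. In Jarid2 + Aebp2 KO 331 rose and 312 fell (643 in all), with 108 and 132 past 2-fold. In Pcl1-3 + Epop KO 577 rose and 538 fell (1115 in all), with 227 and 321 past 2-fold. These totals rose or fell by over 1.5 times under several settings. For Pcl1-3 KO the total was 461 without WT replicate 1, 751 without WT replicate 2, 651 without its own replicate 1 and 477 without its own replicate 3. For Jarid2 + Aebp2 KO it was 98, 277 and 358 without WT replicates 1, 2 and 3, and 249 and 81 without its own replicates 1 and 3. For Pcl1-3 + Epop KO it was 471, 713 and 722 without WT replicates 1, 2 and 3, and 1864 and 524 without its own replicates 1 and 3. With the replicate number as a block the totals were 2895 for Pcl1-3 KO, 2730 for Pcl1-3 + Epop KO and 2281 for Jarid2 + Aebp2 KO, and with no filter on low counts 2001, 1810 and 1444. With replicates 1 and 2 of every genotype Pcl1-3 + Epop KO had 620 and Jarid2 + Aebp2 KO 327, for which DESeq2 called 1052. The balance of directions in Pcl1-3 + Epop KO was not stable: with only the genotypes compared 34 IDs rose and 121 fell (155 in all), without its own replicate 3 187 rose and 337 fell, and without its own replicate 1 1114 rose and 750 fell.

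Combined losses changed more IDs. In Pcl1-3 + Jarid2 KO 1357 IDs rose and 1159 fell (2516 in all), with 625 and 550 past 2-fold. In Pcl1-3 + Jarid2 + Aebp2 KO 1165 rose and 1037 fell (2202 in all), with 419 and 611 past 2-fold. Expression was gained in 14 and 8 IDs and lost in 48 and 55 by the stricter rule, and the gains were 23 and 16 without WT replicate 2, 7 without Pcl1-3 + Jarid2 KO replicate 3 and 5 without Pcl1-3 + Jarid2 + Aebp2 KO replicate 3. The totals were 1507 and 1379 without WT replicate 1, 1460 without Pcl1-3 + Jarid2 KO replicate 3 and 1409 without Pcl1-3 + Jarid2 + Aebp2 KO replicate 3. With the block they were 4052 and 3851, and with only the genotypes compared Pcl1-3 + Jarid2 KO had 3959.

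The full non-core knockout changed the most IDs among the non-core knockouts: 2510 rose and 2313 fell, with 1205 and 937 past 2-fold. Of the 1172 IDs under 0.5 CPM in WT 335 rose (28.6%), and of 991 under 0.5 CPM in this knockout 295 fell (29.8%), with the same effect of the filter; without it the shares were 2.77% and 2.27%. By the stricter rule 73 IDs gained and 87 lost expression. Of the 3038 IDs risen in Suz12 KO, 1094 also rose here (521 for independent lists), and of the 2683 fallen, 868 also fell (424). Both comparisons use the same WT libraries, so part of that excess may come from them.

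**Figure D4:**
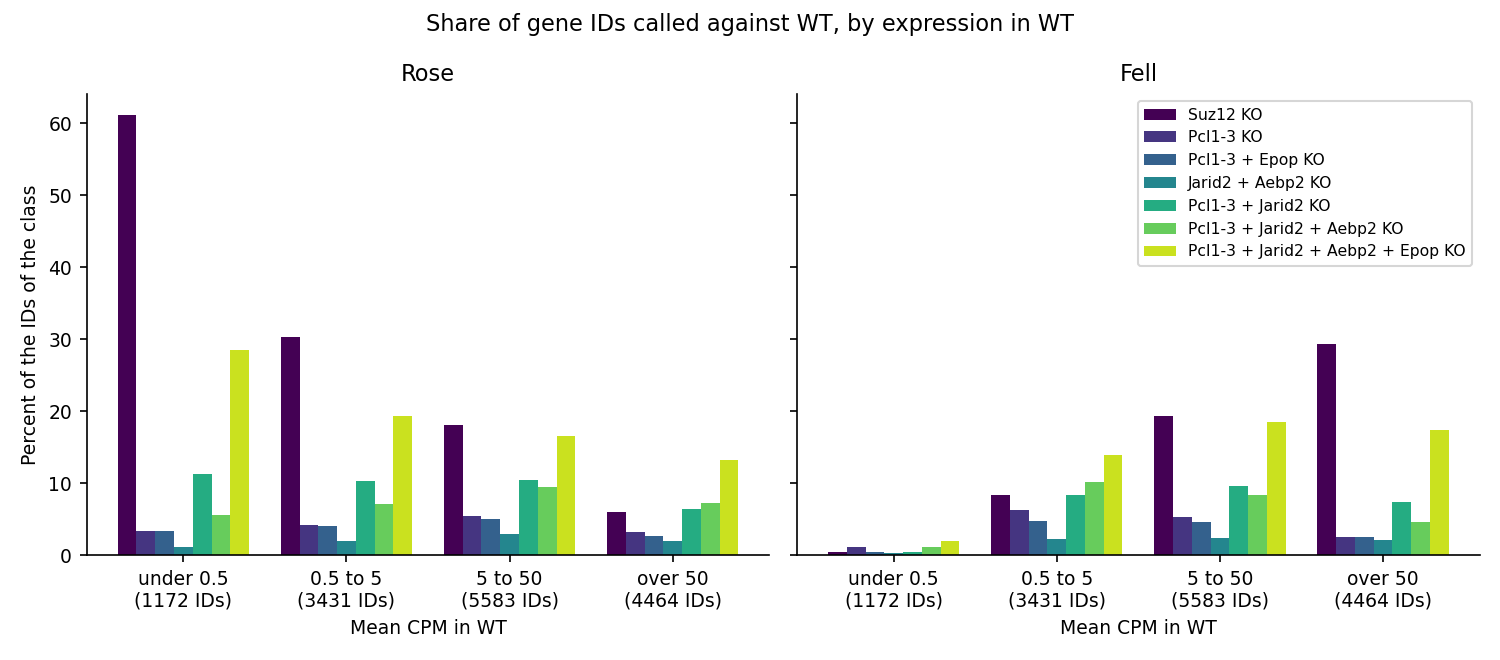
Percent of gene IDs that rose (left) or fell (right) against WT in each knockout (vertical axis), by mean CPM in WT (horizontal axis, number of IDs in parentheses; WT also serves as control). In Suz12 KO 61.1% of the 1172 IDs under 0.5 CPM rose and in the full non-core knockout 28.6%, shares that the filter raises because IDs silent in every genotype are left out.

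A direct comparison asks whether losing these 6 non-core subunits equals losing SUZ12. The genotypes differed: 3040 IDs were higher and 3254 lower in the full non-core knockout than in Suz12 KO, with 960 and 1948 past 2-fold (edgeR quasi-likelihood). Of the 3038 IDs risen in Suz12 KO, 1813 were lower, 141 higher and 1084 not past the test. Of the 2683 fallen, 1420 were higher, 144 lower and 1119 not past the test. Conversely, 1055 IDs rose in the full non-core knockout, were higher there than in Suz12 KO and had not risen in Suz12 KO. Among 2439 IDs called in both against WT, 477 went opposite ways. The sets were chosen in the same Suz12 KO libraries, which favours such directions; in 20 simulations with equal means in both knockouts at most 1 risen ID was past the test and lower and 0 fallen IDs past it and higher. In them 57.0% of risen IDs had a lower and 59.6% of fallen IDs a higher fitted value, against 82.6% and 82.3% observed.

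Similarity to Suz12 KO was measured for each knockout; differences between them were not tested. Over the 5721 IDs called in Suz12 KO, the r of log2 fold changes was 0.173 for Pcl1-3 KO, 0.187 for Pcl1-3 + Epop KO, 0.0760 for Jarid2 + Aebp2 KO, 0.367 for Pcl1-3 + Jarid2 KO, 0.205 for Pcl1-3 + Jarid2 + Aebp2 KO and 0.475 for the full non-core knockout. These r are across IDs, and unchanged groups simulated against the same WT gave 0.52 to 0.54. Simulated covariance was 0.0480 to 0.0482, below the observed 0.0571 to 0.739, although simulated r was higher. The simulated fold changes thus spread less than the observed ones. Their r is no baseline here, and r alone cannot tell similarity from the shared WT. The share of IDs with the same sign was 56.7%, 58.5%, 50.2%, 63.6%, 59.5% and 68.8% in the same order. The simulated 66.8 to 67.8% came from the same simulated fold changes, so it is no baseline for these shares either. Observed minus simulated covariance, which grows with the size of the fold changes, was 0.109, 0.118, 0.00900, 0.353, 0.170 and 0.691 in the same order.

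Adding the loss of Jarid2 to that of Pcl1-3 raised 543 IDs and lowered 375 (918 in all). Of the 543, 284 had also risen in Suz12 KO (113 for independent lists) and 49 had fallen, a comparison that shares no library with this one. Of the 375, 118 had fallen there (68.7 for independent lists) and 82 had risen. The r with the Suz12 effect was 0.286 across IDs. With the replicate number as a block 1949 IDs were called, and with replicates 1 and 2 of every genotype 503. The total was 463 and 571 without Pcl1-3 KO replicates 1 and 3, and 508 and 422 without Pcl1-3 + Jarid2 KO replicates 2 and 3.

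Adding the loss of Aebp2 to that of Pcl1-3 and Jarid2 raised 50 IDs and lowered 82 (132 in all). Of the 82, 48 had risen and 14 had fallen in Suz12 KO, and of the 50, 13 had risen (10.4 for independent lists) and 15 had fallen. The r with the Suz12 effect was −0.295 across IDs, from libraries that are not shared. The Pcl1-3 + Jarid2 + Aebp2 KO libraries also enter the last step, the added loss of Epop, with the opposite sign. Both steps are therefore not independent of each other. The blocked fit called 432 IDs, DESeq2 242, the test with no filter 391 and that with only the genotypes compared 62. The total was 71 and 37 without Pcl1-3 + Jarid2 KO replicates 2 and 3, and 51 and 70 without Pcl1-3 + Jarid2 + Aebp2 KO replicates 1 and 2.

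The loss of Epop was followed in 2 backgrounds. Added to Pcl1-3 loss, with Jarid2 and Aebp2 present, it raised 1 ID and lowered 0 (edgeR; 210 at an unadjusted p under 0.05), against 20 with no filter, 3 by DESeq2, 2 with the block and 0 with only the genotypes compared or with replicates 1 and 2. The 1 call was lost, leaving 0, without Pcl1-3 KO replicate 1, 2 or 3 or without Pcl1-3 + Epop KO replicate 3. Added to the loss of Pcl1-3, Jarid2 and Aebp2, it raised 848 IDs and lowered 799 (1647 in all), with 556 and 270 past 2-fold. The total was 3049 with the block and 937 with only the genotypes compared, of which 563 rose and 374 fell. Of the 848, 528 had risen in Suz12 KO (176 for independent lists), and of the 799, 357 had fallen there (146), again with no shared library; the r with the Suz12 effect was 0.475 across IDs. The total was 1084 without Pcl1-3 + Jarid2 + Aebp2 KO replicate 1 and 1097 without the full non-core knockout replicate 3. The difference between both effects of Epop loss, tested itself as a comparison added after the calls had been seen, passed at 306 IDs, 149 higher and 157 lower; 914 passed with the block, 699 with no filter, 507 by DESeq2, 89 with only the genotypes compared, 193 without Pcl1-3 KO replicate 3 and 201 without the full non-core knockout replicate 2.

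The test of added losses asks whether Pcl1-3 + Jarid2 + Aebp2 KO equals the sum of Pcl1-3 KO and Jarid2 + Aebp2 KO. At 543 IDs the combined loss lay above the sum and at 535 below (1078 in all; 2745 with the replicate number as a block, 1696 with no filter, 543 with replicates 1 and 2). The IDs above had median log2 fold changes of −0.35 in Pcl1-3 KO, −0.43 in Jarid2 + Aebp2 KO and 0.17 in the combined knockout; those below had 0.39, 0.50 and −0.08. WT enters this contrast with the sign opposite to both single knockouts, so a chance value in WT moves the medians in this way too. The total was 494 and 718 without WT replicates 1 and 2, 533, 1621 and 451 without Pcl1-3 KO replicates 1, 2 and 3, 564 and 495 without Jarid2 + Aebp2 KO replicates 1 and 3, and 640 and 639 without Pcl1-3 + Jarid2 + Aebp2 KO replicates 1 and 2.

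The labels were checked by patterns across knockouts, since the targeted genes cannot be found among the IDs. IDs that fell more than 2-fold in each knockout of a gene, with a log2 fold change above −0.5 in the other knockouts, numbered 202 for Suz12, 21 for the Pcl genes, 2 for Jarid2, 1 for Aebp2 and 1 for Epop. By the mirrored rule 531, 6, 1, 0 and 0 IDs rose in the same order. The pattern thus checks the labels only weakly and does not show that any fallen ID is the targeted gene.

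Chromosome 8 carried more SUZ12 peaks per gene than any other autosome: 68.3 per 100 protein-coding genes, against a median of 35.2 and a range of 23.7 to 54.7. For PCL2 the values were 161 against 90.9, and for JARID2 30.5 against 23.8 (14.7 to 34.7). Of chromosome 8 genes 34.6% were near SUZ12, against 20.9% on the other autosomes (Fisher's exact test, two-sided, p = 2.44e-23); for JARID2 12.8% were, and the difference did not pass (p = 0.464). The X chromosome had 9.94, 24.4 and 10.8 peaks per 100 genes for SUZ12, PCL2 and JARID2.

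**Figure D5:**
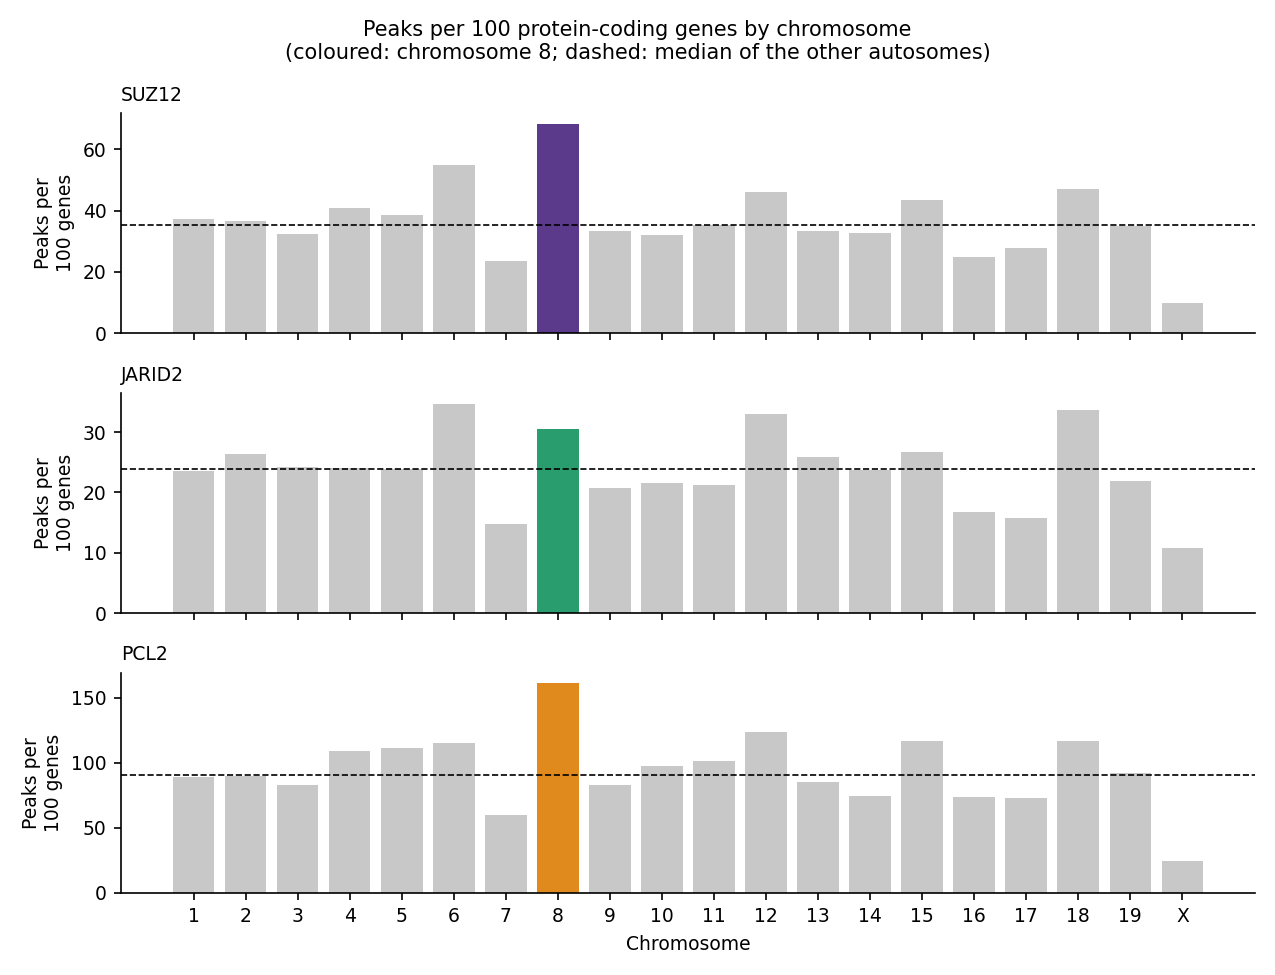
Peaks per 100 protein-coding genes (vertical axes, bars start at 0) on each autosome and X (horizontal axis) for SUZ12, JARID2 and PCL2, with chromosome 8 coloured and the median of the other autosomes dashed. For SUZ12 chromosome 8 stands at 68.3 against a median of 35.2.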

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

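Of the tests in this part, those of the difference between both effects of Epop loss, its splits, the splits within replicate numbers, the permutations of residuals and the spread of each comparison fitted alone were chosen only after the result was seen.

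Epop loss passed the test at more IDs where Jarid2 and Aebp2 were also lost, and the difference between both effects passed at 306 IDs, a difference between groups. Unequal spread stays open: the ratio of median standard errors, 0.992, met the rule written beforehand for excluding it, but that verdict was set aside afterwards because 1 dispersion per ID holds the ratio near 1; with each comparison fitted alone it was 1.06, with a biological coefficient of variation of 22.3% against 17.7%, and the difference passed at 89 IDs when only the genotypes compared were fitted. A change of the full non-core line unrelated to loss of SUZ12 is argued against by r = 0.648 with the Suz12 effect. This r covers the IDs past the threshold for Epop loss in that background and shares no library. A change of the Pcl1-3 + Jarid2 + Aebp2 KO line away from the Suz12 pattern would also give a positive r. The step into that line, the added loss of Aebp2, had r −0.260 over its own IDs past the threshold. The r therefore cannot tell Epop loss from a difference of either line. Splits of the same 12 libraries do not measure chance alone here. Of 100 drawn splits 14 gave as many IDs (highest other 1790). Of 100 that kept 1 library of each replicate number in each group 8 did (highest other 1673). With the block 8 of these did (real 914, highest other 3132). Other splits with as many IDs carried the separate effects of the genotypes more, on average, than the rest. Their mean shares of the contrast were 42.7% against 16.3% among the drawn and 31.7% against 17.3% within replicate numbers. The lowest carried 11.1%, so these effects do not account for all such splits. With these effects held, 4 of 100 permutations of the residuals gave as many IDs (limma, real 126, highest other 1885), close to the bound of 5. Within replicate numbers only the real 1 did (highest other 0). The last count argues against chance between libraries, but together these counts do not exclude it. That EPOP matters more when JARID2 and AEBP2 are gone stays open as a hypothesis, beside differences between the cell lines that the labels do not describe.

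The combined loss of Pcl1-3, Jarid2 and Aebp2 differed from the sum of the separate losses at 1078 IDs. Of 100 drawn splits 3 gave as many, the highest other 1760. Of 100 splits that kept 1 library of each replicate number in each group only the real 1 did. This held without the block (highest other 271) and with it (real 2745, highest other 1055). By the rule on correlations, though, WT did not pair by number with these knockouts. With the separate effects held, residuals were permuted over all 12 libraries, and 5 of 100 gave as many IDs (limma, real 1103, highest other 3243). Within replicate numbers only the real 1 did (highest other 0). Splits carry the separate effects too. In the 2 other drawn ones with as many IDs these made up 77.8% of the contrast on average, against 18.6% in the rest. The splits thus do not measure chance alone, and the first permutation does not exclude it. Leaving out single libraries gave 451 to 1621 IDs: 494 and 718 without WT replicates 1 and 2, 533, 1621 and 451 without Pcl1-3 KO replicates 1, 2 and 3, 564 and 495 without Jarid2 + Aebp2 KO replicates 1 and 3, and 640 and 639 without Pcl1-3 + Jarid2 + Aebp2 KO replicates 1 and 2.

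For the 12 comparisons of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05. In 11 of them 1 split, the real one, gave as many IDs and the highest other gave 0: 5721, 1274, 1115, 643, 2516, 2202 and 4823 for the knockouts against WT in the order of the plot of calls, 6294 for the full non-core knockout against Suz12 KO, and 918, 132 and 1647 for the added losses of Jarid2, Aebp2 and Epop. For Epop loss added to Pcl1-3 loss the real split gave 1 and 2 of 10 gave as many; the highest other, 1911, set replicates 1 and 2 of Pcl1-3 + Epop KO with replicate 2 of Pcl1-3 KO against the rest, which points to a structure of the samples. The splits that parted all same-numbered libraries of that comparison gave at most 0 besides the real one.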

How the results depend on the processing

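Chosen only after the result was seen were the comparison of both Epop effects, the use of replicates 1 and 2 alone, peaks wider than the median only (below, wider peaks) all other settings for fixed lists near peaks, and the counts of nearly silent IDs by class without a filter. The planned tests of list shifts in RNA (other correlations, fry, the block) and of bound genes among changed genes (5 kb, matched background, the block) were not run, as IDs have no symbols, nor was a choice of the stronger peaks, as the lists have no score.

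With DESeq2's size factors within edgeR no count moved by more than 1.5 times. DESeq2 itself called 5468 of the 5721 IDs of Suz12 KO in the same direction. The replicate block kept all 5721 and called more, 7259 in all. It called 6396 for the full non-core knockout against WT and 7732 for that knockout against Suz12 KO. Of 119 results of the 4 named IDs under alternatives, 0 calls were lost, 1 setting giving no value for ENSMUSG00000071424.10.

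Below, the comparisons keep the names of the report, with "added" for a further loss. The cause was not tested for any move, except that a fold threshold calls fewer IDs by construction. DESeq2 called 1052 IDs for Jarid2 + Aebp2 KO, 242 for added Aebp2 loss, 507 for the Epop difference and 3 for Epop loss added to Pcl1-3 loss. Without a filter the counts were 2001 for Pcl1-3 KO, 1810 for Pcl1-3 + Epop KO, 1444 for Jarid2 + Aebp2 KO, 20 for Epop loss added to Pcl1-3 loss, 391 for added Aebp2 loss, 1696 for the sum of losses and 699 for the Epop difference. With the block they were 2895 for Pcl1-3 KO, 2730 for Pcl1-3 + Epop KO, 2281 for Jarid2 + Aebp2 KO, 4052 for Pcl1-3 + Jarid2 KO and 3851 for Pcl1-3 + Jarid2 + Aebp2 KO. By the rule that each same-numbered correlation exceed 0.1, the replicate numbers of these knockouts did not pair with WT. The mean same-numbered correlation of WT with all knockouts was still 0.159, so WT paired more weakly rather than not at all. Among knockouts the block gave 2 for Epop loss added to Pcl1-3 loss, 1949 for added Jarid2 loss, 432 for added Aebp2 loss, 3049 for Epop loss added last, 2745 for the sum of losses and 914 for the Epop difference.

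With a log2 fold change over 1 the counts were 2617, 620, 548, 240, 1175, 1030 and 2142 for the knockouts against WT in the report's order, 2908 for the full non-core knockout against Suz12 KO, 480, 79 and 826 for added Jarid2, Aebp2 and last Epop loss, and 563 for the sum of losses. With only the genotypes compared they were 155 for Pcl1-3 + Epop KO, 3959 for Pcl1-3 + Jarid2 KO, 62 for added Aebp2 loss, 937 for Epop loss added last, 89 for the Epop difference and 0 for Epop loss added to Pcl1-3 loss. With replicates 1 and 2 alone they were 620 for Pcl1-3 + Epop KO, 327 for Jarid2 + Aebp2 KO, 0 for Epop loss added to Pcl1-3 loss, 503 for added Jarid2 loss and 543 for the sum of losses.

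Leaving out each library gave 4651 to 5128, 461 to 1527, 471 to 1864, 81 to 822, 1460 to 2098, 1379 to 2040 and 3578 to 4978 IDs for the knockouts against WT in the report's order. For the full non-core knockout against Suz12 KO it gave 5358 to 6215, for added Jarid2 loss 422 to 960, added Aebp2 loss 37 to 113, Epop loss added last 1084 to 2074, Epop loss added to Pcl1-3 loss 0 to 1, the sum of losses 451 to 1621 and the Epop difference 193 to 426. For the r with Suz12 KO only WT and Suz12 KO libraries were left out, so the spread from each other knockout's own libraries is not covered. The r ran from 0.151 to 0.20, 0.165 to 0.213, 0.0435 to 0.114, 0.356 to 0.385, 0.199 to 0.228 and 0.471 to 0.487 for the 6 other knockouts. Over all IDs r was 0.295 for Pcl1-3 + Jarid2 KO and 0.393 for the full non-core knockout. Of 756 derived counts under alternatives, 92 moved; that of IDs nearly silent in WT that rose in Suz12 KO was 1405 without a filter, where more IDs are tested. The overlaps of added losses with the Suz12 effect, and the sets from the full non-core knockout against Suz12 KO, were not recomputed under alternatives.

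Of SUZ12 peaks, 42.4% (peaks of at least 1 kb) and 55.2% (wider peaks) overlapped JARID2, and 96.3% (overlap of at least 0.5 of either peak), 91.2% (1 kb) and 99.2% (wider) PCL2. Of JARID2 peaks, in the same order of 3 settings, 88.0%, 97.8% and 92.3% overlapped SUZ12 and 93.4%, 98.2% and 99.4% PCL2. Of PCL2 peaks, 38.3%, 73.8% and 40.3% overlapped SUZ12, and 35.0% (1 kb) and 24.2% (wider) JARID2. The cause was not tested.

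Of 264 list results under other settings, 16 calls were lost, 6 gained and 17 changed direction (1 of them also lost) relative to other genes; the cause was not tested. All but 1 of the 17 passed in neither setting; germline genes near SUZ12 (wider peaks, 8.70%) had passed before. At 5 kb the others were PRC2 non-core with SUZ12 (25%), cell cycle with PCL2 (42.1%), blood with SUZ12 (31.3%) and JARID2 (18.8%) and heat shock with JARID2 (13.3%). Over the whole gene they were cell cycle with PCL2 (36.8%), blood with SUZ12 (31.3%) and heat shock with JARID2 (13.3%). With peaks of at least 1 kb they were PRC2 non-core with SUZ12 and PCL2 (12.5% each), blood with PCL2 (12.5%) and heat shock with SUZ12 and PCL2 (20% each), and with wider peaks blood with PCL2 (12.5%) and heat shock with SUZ12 (20%) and PCL2 (26.7%).

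Depth and spread limit what was called: in simulated data 59.7% of 2-fold changes were found for Suz12 KO against WT, so an ID not called is not shown to be unchanged.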

Other observations

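The tests of gene families by symbol stem, of JARID2 and PCL2 within subsets of genes, of more Polycomb target genes on chromosome 8, of an extra copy of it and of numbered rounds were chosen only after the result was seen. Among the families, all 14 Nkx and all 6 Irx homeobox genes had a peak of each protein near an end, and 18 of 19 Wnt ligand genes had SUZ12 (Wnt8b did not). SUZ12 was near 16 of 19 Sox genes, without Sox2, Sox12 and Sox15, near 8 of 9 Pax genes, without Pax4, near 11 of 12 Lhx genes, without Lhx4, and near 5 of 6 Gata genes, without Gata1. Potassium channel genes (Kcn) had SUZ12 at 54 of 94 (adjusted p = 4.85e-14, Fisher's exact test) and clustered protocadherins at 30 of 57, where PCL2 had 47 and JARID2 13. The test takes genes as independent, which neighbours in a gene cluster may not be. Klf factors had SUZ12 at 3 of 17 (adjusted p = 1), histones at 6 of 104, and olfactory receptors at 4 of 1106 (adjusted p = 8.02e-105, fewer than other genes).

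Within subsets of genes, JARID2 and PCL2 peaks did not always go with SUZ12 peaks. The PCL2 list holds 20003 peaks against 7796 for SUZ12, so PCL2 without SUZ12 may only reflect the longer list. Of all genes near SUZ12, 54.0% were also near JARID2; of the Hox genes among them 35 of 36 were (adjusted p = 1.39e-07), of the neural regulators 26 of 28, and of the mesoderm and of the signalling genes 23 of 25 each. Germline genes had 3 of 10 (adjusted p = 0.350, Fisher's exact test), which does not pass. Of genes without SUZ12, 19.1% were near PCL2. Among the germline genes it was 8 of 13 (Fisher's exact test, adjusted p = 0.0186), including Mael, Stra8 and Sycp2. Among the Hox genes it was 3 of 3 and among the signalling genes 4 of 5 (same test, adjusted p = 0.0484 each). Those Hox genes lie in the Hoxc cluster, and Hoxc4 holds a SUZ12 peak inside it. Over all germline genes the PCL2 call ended with peaks of at least 1 kb (same test, adjusted p = 0.611). The subset tests used all peaks within 1 kb only and take genes as independent.

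Peaks of SUZ12 and PCL2 were denser on chromosome 8 than on other autosomes. Tandem 5S ribosomal RNA genes are argued against, since the ratio to the median autosome was 1.94 with and 1.91 without that region. More Polycomb target genes there are argued against by the JARID2 list, though JARID2 marks only part of the targets. The odds that a SUZ12 peak rather than a JARID2 peak lies on chromosome 8 were 1.46 (95% interval 1.27 to 1.68, with peaks taken as independent). An extra copy of chromosome 8 in the cells behind the SUZ12 and PCL2 lists stays open. Of its 13 windows of 10 Mb, 92.3% had more SUZ12 peaks per JARID2 peak than the other autosomes. The windows show that the excess runs along the chromosome. They otherwise restate it and cannot tell an extra copy from another chromosome-wide cause. Which cells each list came from is not given in the sources used here. The share on chromosome 8 was higher among narrow peaks (10.8%) than among wide ones (9.35%), the direction an extra copy predicts. That difference did not pass (Fisher's exact p = 0.163), so the test cannot tell. No biological explanation from the design's groups was tested.

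Libraries with the same replicate number deviated together from their genotype means. Sequencing depth is argued against as the cause: r of the first component of the deviations with log2 total counts was 0.0605 over 24 libraries (95% interval −0.351 to 0.453; permutation p = 0.773; rho −0.148, permutation p = 0.488; r −0.237 without the 2 farthest libraries). Rounds of growth or library making that share a number stay open and were not tested apart from the pattern itself: the mean r of 0.295 for same-numbered libraries, and the difference of 0.442 from other libraries, restate it, and taking deviations from means of 3 libraries fixes the r of the others. The labels name no such rounds.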
